A study of Homo sapiens with 9 samples.

How the data were processed

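RNA sequencing was analysed for 9 libraries of Tregs (regulatory T cells) of the effector memory type, taken from human blood. Per the labels' protocols, the cells were sorted by flow cytometry out of all CD4+ T cells and kept for 3 h with phosphate-buffered saline (PBS, the control), high-density lipoprotein (HDL) or linoleic acid (LA). The labels give 700 ug/ml and a protein basis that can only hold for HDL, so the amount of LA is not certain. Each of 3 healthy donors gave 1 library per treatment, so each group held 3 libraries. Per the labels' protocols, full-length cDNA libraries were made from low RNA input with a kit that does not keep the strand, so reads from a gene and from an overlapping or antisense gene could not be told apart.

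The deposited table holds raw read counts per gene symbol, with 1 column per library. Per the submitters' processing notes, FastQC 0.12.1, Trim Galore 0.6.7, STAR 2.6.1d, Salmon 1.10.1 and the genome build hg38 were used. The notes state neither the gene annotation nor whether the counts were rounded from Salmon estimates. All 9 columns were used. The table had 26475 gene symbols and 0 duplicated symbols. Genes on the sex chromosomes that could reveal a donor's sex (99 symbols) were left out before any test, and rearranged receptor segments, HLA genes and other genes commonly set by germline variants were not named.

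Total counts ran from 11818759 in HDL replicate 1 to 14592341 in PBS replicate 3. Genes were kept by the edgeR function filterByExpr with its minimum count of 10, which left 12091 genes. The median standard error (SE) of a log2 fold change between LA and PBS was 0.307 over all tested genes and 0.166 over genes with a mean of at least 50 CPM (read counts scaled to a common library size of 1e6). CPM of genes were scaled with the trimmed mean of M values (TMM), and summed CPM of gene lists were scaled on total counts. Limits for a count of 0 were set at 3 counts and cover counting error only. Gene coordinates came from the RefSeq annotation of GRCh38.p14 and were looked up by symbol.

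All 9 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with the group as the term and no donor term. The labels give the donor of each library, but no text states how the donors were treated in a test, and the fit without a donor term was set before the data were examined. Contrasts were tested with edgeR's quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors were computed from the fold change and its F statistic. The common dispersion was 0.129, and 0.0729 with the donor as a block. The labels say that libraries with the same number come from the same donor, so the numbers pair the libraries. Deviations from the group means correlated at 0.205 to 0.343 in the 9 same-donor pairs of libraries and at -0.238 to -0.046 in the 18 different-donor pairs.

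The alternatives were the donor as a block, the donor as a random effect in limma-voom (limma 3.58.1), DESeq2 1.42.0 with and without the block, other scalings, other filters, other thresholds, fits on the 6 libraries of a comparison, and fits without each library. Those were written down before the data were examined. A correction for GC content and transcript length, and the overlap of LA and HDL calls in the other tools, were added after the data had been seen. The correction removed each library's loess trend (span 0.5) on the GC content and length of the longest GENCODE transcript, protein-coding where there was such a transcript. Both were known for 97.01% of tested genes.

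Gene lists were written before the data were examined and covered lipid metabolism, mitochondria, stress responses, survival, Treg and T cell states, translation, and markers of other blood cells. The total was 38 lists with 1079 entries. Of these, 1063 were in the table, 27 of them under an older symbol. The 34 lists with at least 5 tested members were tested with camera in limma with a preset correlation of 0.01. Camera with a correlation estimated from the residuals and fry were run beside it, all with Benjamini-Hochberg adjustment over the lists. Members were also counted at a p "adjusted over the list alone", which repeats the gene tests within each list.

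Genes named in the text followed a rule written before the data were examined. For each comparison these were the 10 genes with the largest log2 fold change in each direction among those past the threshold with a mean of at least 5 CPM and the same direction in all 3 donors, without uncharacterised LOC symbols. They also included up to 4 members of each list past its threshold, taken in order of p from the fits without and with the block, and 15 genes fixed in advance for lipid handling, Treg identity, mitochondria and survival. Where the rule gave fewer than 10 genes in a direction, it drew on the fit with the block, and for LA against PBS it gave none. Some genes picked by the rule are left out of the text. Other named genes were chosen after their values were seen, and the text says so.

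The tests were checked on simulated counts, drawn from the negative binomial distribution with the PBS and donor effects and the gene-wise dispersions of the fit with the block. Of 100 genes changed by a log2 value of 1 between simulated LA and PBS groups of 12091 genes, 31 were recovered without the block and 56 with it. Of 100 genes changed by a log2 value of 2, 59 were recovered without the block and 75 with it. For simulated HDL and PBS groups the numbers were 22 and 47 at 1, and 57 and 74 at 2. Both sizes were placed in the same simulated counts, so each fit had a single number of unchanged genes called, for both sizes together. It was 1 without the block and 9 with it for LA, and 0 and 12 for HDL. Because LA and HDL were compared with the same PBS libraries, 20 simulations of unchanged groups gave the correlation that shared controls produce. Figures were drawn with matplotlib 3.10.9.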

Results

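The transcriptome of primary human effector memory Tregs was measured by RNA sequencing after 3 h with PBS, HDL or LA. Each group held 3 libraries, 1 from each of 3 healthy donors. The mean total count was 13113000 ± 1282000 (SD, n = 3) in PBS, 13036000 ± 947600 in LA and 11954000 ± 187900 in HDL. At least 1 count was found for 14481 ± 77.3 genes in PBS, 14617 ± 240.5 in LA and 14549 ± 166 in HDL. TMM scaling factors averaged 0.950 ± 0.0331 in HDL against 1.02 ± 0.0157 in PBS and 1.03 ± 0.0201 in LA. In a principal component analysis of log CPM, components 1 and 2 held 21.9% and 19.5% of the variance, and HDL replicate 1 had the highest score on component 1 (69.9, against 21.0 for the next library, HDL replicate 2).

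The comparison of LA with PBS asked whether exposure to this polyunsaturated fatty acid altered transcripts of the cells, whose mitochondrial function and survival are the subject of the series. FOXP3, the transcription factor that defines Tregs, was at 239 ± 90.9 CPM in LA and 212 ± 53.25 CPM in PBS (SD, n = 3), with a log2 fold change of 0.17 ± 0.37 (SE). IL2RA and CTLA4, both surface proteins of Tregs, had log2 fold changes of -0.04 ± 0.13 and -0.23 ± 0.16. CPT1A, which admits fatty acids to mitochondrial oxidation, was at 11.85 ± 1.97 CPM in LA and 9.86 ± 5.20 CPM in PBS, and PLIN2, the lipid droplet coat protein, was at 189 ± 38.7 and 190 ± 32.4 CPM. Their log2 fold changes were 0.26 ± 0.35 and -0.01 ± 0.24. None of these genes passed the threshold. With the donor as a block, FOXP3, IL2RA and CTLA4 had values of 0.11 ± 0.13, -0.03 ± 0.10 and -0.23 ± 0.13. CPT1A and PLIN2 had 0.34 ± 0.28 and -0.02 ± 0.11 with the block, and none of the genes passed there either.

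Among the other genes fixed in advance, the cholesterol exporter ABCA1 had a log2 fold change of 0.52 ± 1.28 between LA and PBS at a mean of 1.72 CPM in PBS, too imprecise to exclude a large change in either direction. The survival genes BCL2 and MCL1 had values of -0.32 ± 0.17 and 0.05 ± 0.19, and the pro-apoptotic BCL2L11 had -0.08 ± 0.29. TFAM, which maintains mitochondrial DNA, had -0.13 ± 0.18. With the block, BCL2, MCL1, BCL2L11 and TFAM had values of -0.32 ± 0.16, 0.02 ± 0.16, -0.04 ± 0.24 and -0.14 ± 0.16. ABCA1 stayed imprecise with the block, at 0.98 ± 1.33. The adjusted p of edgeR was 1 for each of these tested genes. PDK4, SCARB1 and PPARGC1A had too few counts to be tested.

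Between LA and PBS, 0 of 12091 genes passed the threshold in edgeR, with or without the donor as a block, and 0 passed in limma-voom. An unadjusted p below 0.05 was found for 227 genes without the block and 489 with it, against 605 if p-values were evenly spread. The fit without the block left donor differences in its error, which raises its p-values. Its count of 227 therefore cannot be read as a level below chance. DESeq2 called 1 gene without the block and 5 with it. These genes, chosen after their values were seen, were SYS1-DBNDD2 in both fits and ACVR1C, LOC100190986, SERF1A and TTN in the fit with the block. ACVR1C, an activin receptor, was at 3.61 ± 2.355 CPM in LA and 0.398 ± 0.4996 CPM in PBS, and its DESeq2 log2 fold change with the block was 3.48 (adjusted p = 0.0489). TTN, the sarcomere protein titin, was at 139 ± 72.1 and 68.65 ± 3.556 CPM, with a log2 fold change of 0.91 (adjusted p = 0.0428). The uncharacterised LOC100190986 had 1.45 (adjusted p = 0.00509). ACVR1C, TTN and LOC100190986 were higher with LA in 3 of 3 donors. SYS1-DBNDD2 had a count of 0 in every LA library, which allows up to 0.216 to 0.249 CPM. It is a readthrough transcript whose reads overlap those of 2 other genes, and SERF1A shares nearly its whole sequence with SERF1B, so both are uncertain.

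None of the 34 fixed lists passed between LA and PBS, and the smallest adjusted p of camera was 0.139. It was shared by the nuclear-encoded respiratory chain, with a median log2 fold change of -0.05 over 77 genes, and the mitochondrial ribosome, with -0.06 over 75 genes. Targets of PPAR, the nuclear receptors activated by fatty acids, had a median of 0.04 over 15 genes (adjusted p = 0.567). The anti-apoptotic list had a median of 0.04 but a mean of -0.05 over 16 genes, with the test pointing down (adjusted p = 0.378). Without PBS replicate 2 the respiratory chain and the cytosolic ribosomal proteins passed as lower in LA (adjusted p = 0.0224 for both), and without LA replicate 1 the respiratory chain (adjusted p = 0.00388) and the mitochondrial ribosome (adjusted p = 0.0260) did. These values used the preset correlation, and an estimated correlation was not run in these fits. With all libraries and an estimated correlation, the adjusted p was 0.945 for the respiratory chain and the ribosomal proteins and 0.939 for the mitochondrial ribosome. At a log2 change of 1, simulated LA genes were recovered at 31% without the block and 56% with it. At 10 CPM or more these shares were 46.9% and 82.8%. Changes of that size in single genes could have been missed, above all without the block or at low counts.

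The comparison of HDL with PBS asked which transcripts changed with the lipoprotein. Genes of the heat shock response (17 of 20) and of the NRF2 antioxidant response (8 of 23) rose, and these were the 2 lists that also passed with an estimated correlation. HMOX1, which degrades heme, rose from 0.302 ± 0.362 to 111 ± 58.9 CPM (SD, n = 3), a log2 fold change of 8.48 ± 0.74 (SE, adjusted p = 0.000145). Its PBS counts were 0, 9 and 3, so the size of this fold is uncertain. GCLM, a subunit of the enzyme that limits glutathione synthesis, rose 7.89-fold from 22.2 ± 1.04 to 175 ± 21.9 CPM (log2 2.98 ± 0.16, adjusted p = 7.92e-06). ARRDC3, an arrestin domain protein, rose 8.69-fold from 331 ± 37.5 to 2873 ± 541 CPM (log2 3.12 ± 0.21, adjusted p = 2.09e-05). These genes lie at 35381096 to 35394207 on chromosome 22 (HMOX1), 93885199 to 93909430 on chromosome 1 (GCLM) and 91368631 to 91383317 on chromosome 5 (ARRDC3) of GRCh38, and all 3 are annotated as protein-coding.

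The other genes with the largest increases were the inducible heat shock genes HSPA1B (log2 3.21 ± 0.38, adjusted p = 0.00135), HSPA6 (3.01 ± 0.68, adjusted p = 0.048) and HSPA1A (2.69 ± 0.18, adjusted p = 2.09e-05). They were joined by the quinone reductase NQO1 (2.46 ± 0.39, adjusted p = 0.00801), C7orf50 (2.42 ± 0.22, adjusted p = 0.000218), the chaperone HSPH1 (2.36 ± 0.44, adjusted p = 0.0203) and the microRNA host transcript MIR22HG (2.30 ± 0.46, adjusted p = 0.0284). HSPA1A and HSPA1B are nearly identical, so the division of reads between them is uncertain. Among the largest decreases were those of ABI3, an adaptor of the actin cytoskeleton (from 29.4 ± 5.51 to 7.13 ± 1.99 CPM, log2 -2.04 ± 0.27, adjusted p = 0.0031), and CCR2, a chemokine receptor (log2 -1.78 ± 0.26, adjusted p = 0.0054). They were followed by NHLRC2, the inhibitory receptor PVRIG, NIPSNAP1, the pore-forming protein GSDMD, the iron regulatory protein ACO1, ARHGAP19 and MAGED1, with log2 fold changes from -1.77 to -1.35 and adjusted p from 0.00529 to 0.0474. The naming rule required each of these genes to change the same way in 3 of 3 donors, so that agreement is not a separate result.

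**Figure D1:**
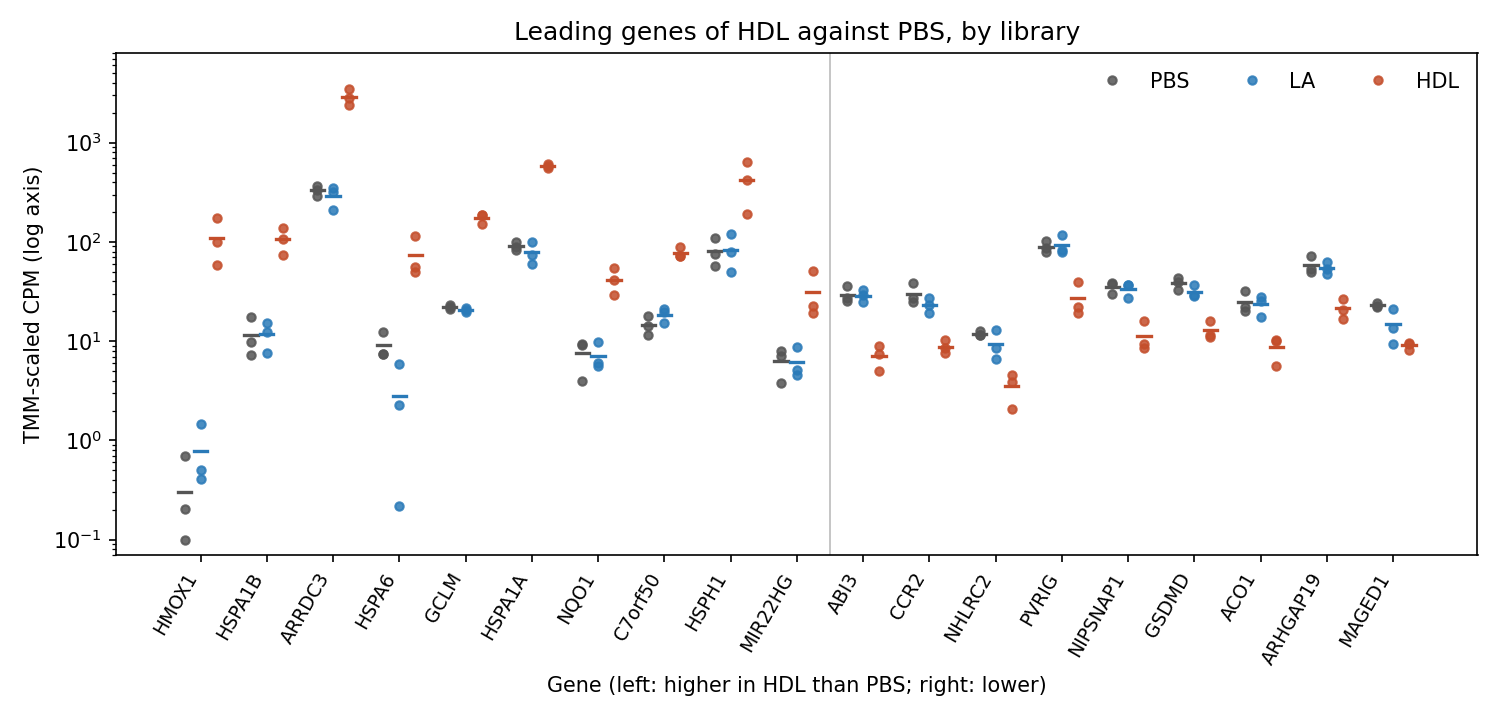
TMM-scaled CPM on a log axis for 19 of the genes with the largest changes between HDL and PBS, 10 that rose and 9 that fell. Points are the 3 libraries of each group and bars are the group means; values below 0.1 CPM are drawn at 0.1 (HMOX1 in 1 PBS library), and the HDL libraries sit apart from PBS for each gene, as for GCLM at 175 against 22.2 CPM.

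Of the 20 tested genes of the heat shock list, 17 rose and 0 fell with HDL, with a median log2 fold change of 1.53, and 19 rose when adjusted over the list alone. HSP90AB1, a constitutive HSP90, rose from 694 ± 29.3 to 2068 ± 123.5 CPM (log2 1.57 ± 0.09, adjusted p = 1.35e-05), and HSPA8, the constitutive HSP70, from 930 ± 58.3 to 2770 ± 160 CPM (1.57 ± 0.10, adjusted p = 1.35e-05). The cochaperone DNAJA1 rose by log2 1.66 ± 0.15 (adjusted p = 0.000200). The list's adjusted p was 9.26e-71 in camera and 0.000607 with an estimated correlation. In the NRF2 list 8 of 23 genes rose and 0 fell, and 12 rose when adjusted over the list alone, with a median of 0.93. Besides HMOX1, GCLM and NQO1, the iron storage subunit FTL rose from 2614 ± 108 to 6559 ± 153 CPM (1.33 ± 0.09, adjusted p = 2.09e-05) and the thioredoxin reductase TXNRD1 from 181 ± 20.4 to 606 ± 71.2 CPM (1.74 ± 0.13, adjusted p = 4.73e-05). The adjusted p of the list was 8.70e-22, and 0.0117 with an estimated correlation.

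The list of immediate early and T cell receptor response genes passed with HDL (median 0.43, adjusted p = 0.000177; adjusted p = 0.271 with an estimated correlation). In it 5 of 30 genes rose, and 7 when adjusted over the list alone. The activation marker CD69 rose by log2 1.35 ± 0.25 (adjusted p = 0.0203) and IRF4 by 1.48 ± 0.22 (adjusted p = 0.00532). KLF6 rose by 1.09 ± 0.13 (adjusted p = 0.00148) and the phosphatase DUSP1 by 1.65 ± 0.33 (adjusted p = 0.0303). In the NF-kB list (median 0.40, adjusted p = 0.00215; adjusted p = 0.158 with an estimated correlation) 1 of 23 genes rose, REL at 1.02 ± 0.18 (adjusted p = 0.0148), and 3 rose when adjusted over the list alone. With the donor block 6 rose, among them NFKBIA (adjusted p = 0.000193), SOD2 (adjusted p = 0.000704) and TNF (adjusted p = 0.00495). In the list of ATF4 targets, the integrated stress response (median 0.38, adjusted p = 0.00300; adjusted p = 0.373 with an estimated correlation), 2 of 30 genes rose, the amino acid transporter subunit SLC3A2 (1.69 ± 0.12, adjusted p = 4.42e-05) and DDIT3 (0.97 ± 0.21, adjusted p = 0.0402). Adjusted over the list alone, 4 rose and 1 fell; with the block, 5 rose, SLC38A2 among them (adjusted p = 0.00198), and 1 fell, the mTORC1 inhibitor DDIT4 (log2 -1.64, adjusted p = 0.000307).

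The list of nuclear-encoded respiratory chain genes was lower with HDL, with a median of -0.18 over 77 genes (adjusted p = 9.00e-05; adjusted p = 0.523 with an estimated correlation). In it 3 genes fell and 0 rose, and 5 fell when adjusted over the list alone. These were the complex I subunits NDUFB7 (-1.07 ± 0.19, adjusted p = 0.0193), NDUFS7 (-0.83 ± 0.16, adjusted p = 0.0235) and NDUFC2 (-0.77 ± 0.16, adjusted p = 0.0327), and with the block 10 fell and 1 rose, NDUFV2 (adjusted p = 0.0135). The tricarboxylic acid cycle list had a median of -0.15 (adjusted p = 0.00300; adjusted p = 0.158 with an estimated correlation). Of its 22 genes 3 fell, PDHB (-0.89 ± 0.15, adjusted p = 0.0104), MDH2 (-0.85 ± 0.16, adjusted p = 0.0203) and SUCLG2 (-0.89 ± 0.19, adjusted p = 0.0354). The number was 4 when adjusted over the list alone. With the block 5 fell, SUCLA2 among them (adjusted p = 0.0103). The mitochondrial ribosome list had a median of -0.22 over 75 genes (adjusted p = 0.00215; adjusted p = 0.373 with an estimated correlation), although the 1 gene past the threshold, MRPL18, rose (0.71 ± 0.15, adjusted p = 0.0399). Adjusted over the list alone, 1 rose and 1 fell; with the block, 2 rose, MRPS6 among them (adjusted p = 0.0216), and 10 fell, such as MRPL57 (adjusted p = 0.0116) and MRPL35 (adjusted p = 0.0215). The 13 respiratory chain genes encoded in mitochondrial DNA had 0 entries in the table.

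Of the other lists, 0 of 26 passed in camera between HDL and PBS in the main fit, and the block added the lysosome and autophagy list (median 0.15, adjusted p = 0.0378) and the naive and central memory list (median 0.17, adjusted p = 0.0171). Both were at adjusted p = 0.308 with the block and an estimated correlation. Without the block, camera passed the naive and central memory list as higher when PBS replicate 1 was left out (adjusted p = 0.00934). With no filter it passed that list (adjusted p = 0.0371) and, as lower, fatty acid oxidation (adjusted p = 0.0153). Fry without the block passed 6 of the 26. These were PPAR targets (median 0.37; adjusted p = 0.0463 in fry and 0.156 in camera), fatty acid oxidation (median -0.16; 0.0463 and 0.102), pro-apoptotic genes (median 0.23; 0.0375 and 0.132), effector cytokines (median 0.40; 0.0375 and 0.260), lipid peroxidation and ferroptosis (median 0.21; 0.0404 and 0.143) and metallothioneins and zinc response (median -0.94; 0.0314 and 0.169). With the block, fatty acid oxidation (adjusted p = 0.102), effector cytokines (0.0550) and metallothioneins (0.102) did not pass in fry. The other 3 did, at adjusted p of 0.0372, 0.0292 and 0.0305 for PPAR targets, pro-apoptotic genes and ferroptosis. Fry with the block also passed the lysosome (adjusted p = 0.0117), naive and central memory (0.0195), interferon response (0.0117), SREBP1 target (0.0292) and conventional CD4 T cell (0.0117) lists. Camera with the block pointed down for the interferon response and SREBP1 target lists and up for the others of these. In the SREBP1 target list 0 of 14 genes passed, with or without the block. In camera without the block, SREBP2 targets had a median of -0.03 (adjusted p = 0.648), LXR targets and cholesterol efflux 0.11 (adjusted p = 0.260) and the Treg signature -0.10 (adjusted p = 0.444). FOXP3 was at 185.5 ± 83.4 CPM with HDL (log2 -0.19 ± 0.37), and the values of IL2RA and CTLA4 were 0.27 ± 0.13 and -0.00 ± 0.16. With the block FOXP3 was at -0.29 ± 0.14 (adjusted p = 0.204) and lower in 3 of 3 donors. IL2RA was at 0.27 ± 0.10 with the block (adjusted p = 0.0882) and CTLA4 at -0.00 ± 0.13 (adjusted p = 0.993). PLIN2 at 0.83 ± 0.24 and CPT1A at 1.053 ± 0.35 did not pass without the block (adjusted p = 0.0952 and 0.138) and passed with it (adjusted p = 0.000985 and 0.0225). ABCA1, BCL2, MCL1, BCL2L11 and TFAM had values of -0.28 ± 1.29, 0.16 ± 0.17, 0.02 ± 0.19, -0.35 ± 0.29 and 0.14 ± 0.18, with adjusted p from 0.606 to 0.968. The value of ABCA1 changed sign with the block, to 0.64 ± 1.28 (adjusted p = 0.805), and its direction stayed open.

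**Figure D2:**
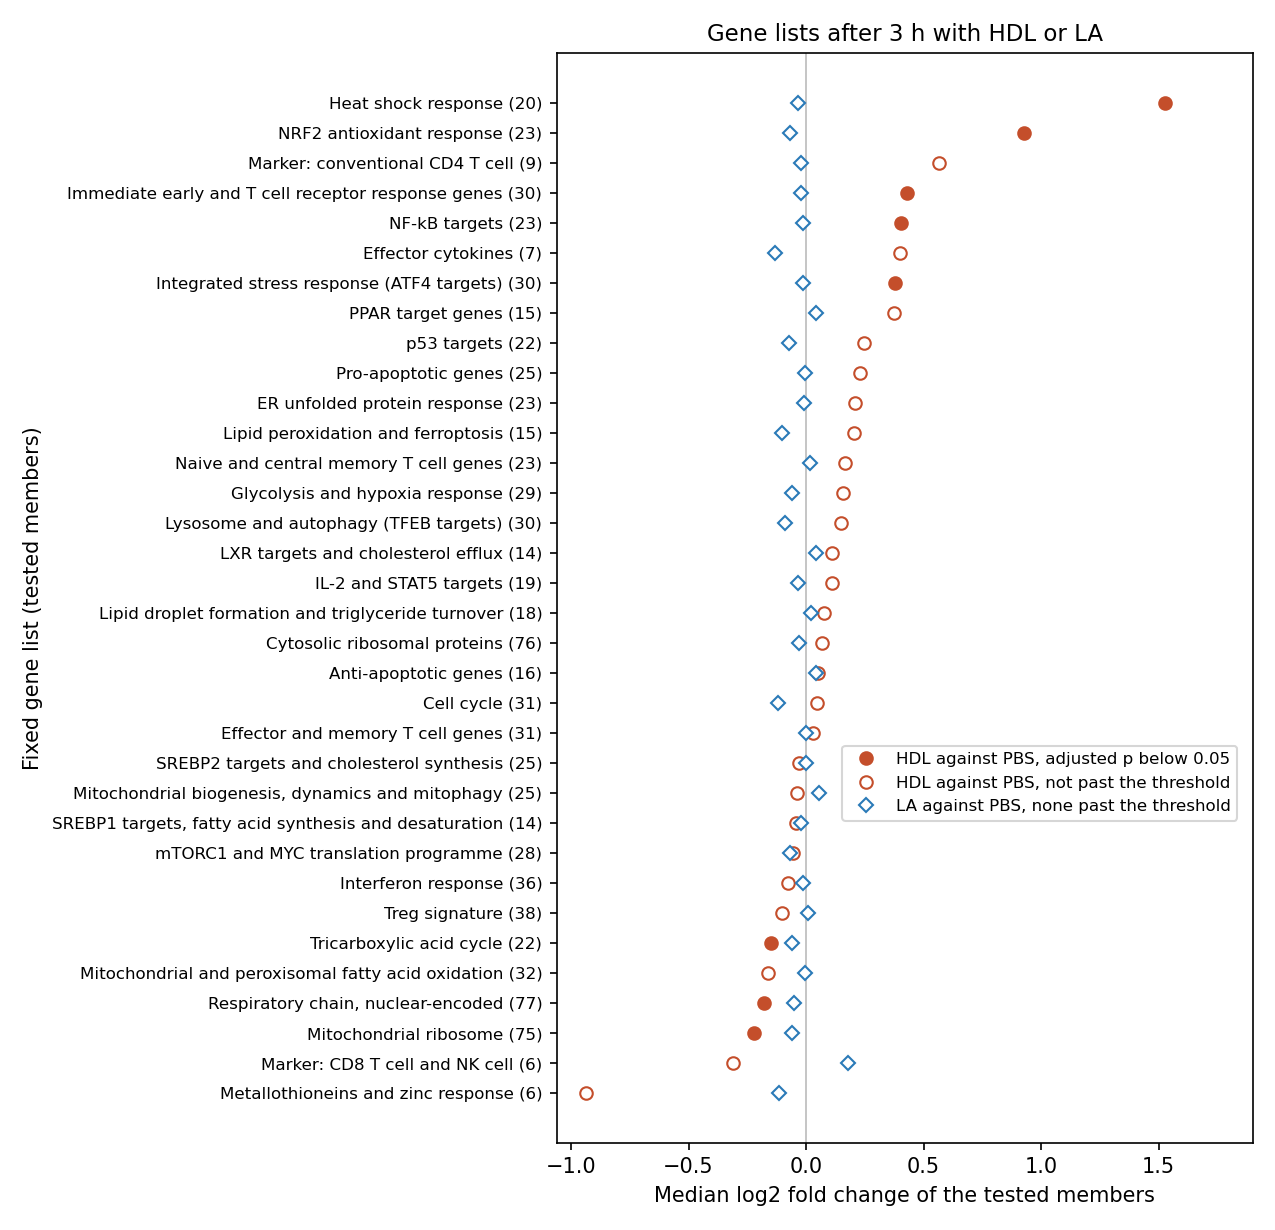
Median log2 fold change of the tested members of the 34 fixed gene lists (number of members in brackets) for HDL against PBS (circles, filled where camera's adjusted p was below 0.05) and LA against PBS (diamonds). The heat shock list is at 1.53 and the NRF2 list at 0.93 for HDL, while the LA medians run from -0.13 to 0.18 and none passed.

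Markers of other blood cells were measured in the same libraries. Of 12 B cell markers measured, 4 had enough counts to be tested. The B cell marker CD79B, picked after its values were seen, was by itself at 30.4 ± 5.30 CPM in PBS and 16.25 ± 4.05 CPM in HDL. Summed B cell markers were at 39.5 ± 5.44 CPM in PBS, 35.7 ± 4.13 CPM in LA and 18.1 ± 5.13 CPM in HDL. Monocyte and myeloid markers were at 10.1 ± 4.98, 7.25 ± 1.67 and 8.92 ± 5.04 CPM, CD8 and NK cell markers at 24.1 ± 10.1, 27.9 ± 13.2 and 15.9 ± 5.07 CPM, and platelet and erythroid markers at 11.7 ± 5.66, 12.3 ± 9.36 and 18.5 ± 8.82 CPM. Markers of conventional CD4 T cells were at 1855 ± 135, 1830 ± 87.3 and 2368 ± 72.8 CPM. Between HDL and PBS, 1 of the 9 tested was higher without the block, and with it 2 were higher and 1 lower. That list was at adjusted p = 0.131 in camera and 0.186 in fry. With the block it was at 0.0559 in camera and 0.0117 in fry, and at adjusted p = 0.308 with an estimated correlation. With the block and the correction for GC content and length, camera gave 0.0499. Between LA and HDL the list was at adjusted p = 0.0756 in camera, and at 0.0332 without HDL replicate 2, lower with LA.

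In total 146 genes rose and 92 fell with HDL against PBS (238 of 12091), of which 62 and 42 changed at least 2-fold. The donor block gave 699 higher and 675 lower, among them all 238 in the same direction, and DESeq2 called 931. Under total-count scaling, which moved the median of all genes by -0.102, 446 passed and 31.6% of them were higher, against 61.3% under TMM. The count was 81, 104 and 96 without PBS replicates 1, 2 and 3, and 87 and 145 without HDL replicates 2 and 3. Of the genes with the largest changes, 11 passed in each of the 6 fits without a library, and HSPA6, HSPH1, MIR22HG, NHLRC2, NIPSNAP1, ACO1, ARHGAP19 and MAGED1 did not in at least 1 (adjusted p up to 0.167, for HSPA6). The same held for CD69, DUSP1, REL, DDIT3, MRPL18 and the 3 called genes each of the respiratory chain and the tricarboxylic acid cycle. The ATF4 list did not pass without PBS replicate 2 (adjusted p = 0.0604) or HDL replicate 3 (adjusted p = 0.0560), nor the respiratory chain list without HDL replicate 3 (adjusted p = 0.127). The ATF4 median was 0.23 and 0.21 in these fits, against 0.38 with all libraries. For the respiratory chain it was -0.08, against -0.18.

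The direct comparison of LA with HDL tested whether the responses differed. It used the same HDL libraries as the comparison above and was not independent of it. Of the heat shock genes 17 of 20, and of the NRF2 genes 7 of 23, were lower with LA than with HDL. HMOX1 was at 0.789 ± 0.573 CPM in LA and 111 ± 58.9 CPM in HDL (log2 -7.09 ± 0.67, adjusted p = 0.000265), and HSPA6 at 2.78 ± 2.85 and 73.2 ± 36.4 CPM (-4.73 ± 0.75, adjusted p = 0.00756). Their LA counts were 5, 7 and 21 for HMOX1 and 71, 3 and 33 for HSPA6, so the size of both differences is uncertain. Over the alternatives the log2 values ran from -7.87 to -6.60 for HMOX1 and from -5.86 to -4.18 for HSPA6. ARRDC3 was at 292 ± 73.4 and 2873 ± 541 CPM (-3.30 ± 0.21, adjusted p = 1.06e-05) and GCLM at 20.7 ± 0.991 and 175 ± 21.9 CPM (-3.08 ± 0.16, adjusted p = 5.86e-06). HSPA1B, HSPA1A, NQO1, MIR22HG, HSPH1 and AVIL, an actin-binding protein, followed with log2 fold changes from -3.17 to -2.31. Among the largest differences in the other direction were those of ABI3 (2.01 ± 0.27, adjusted p = 0.00297), H2AFY2, a histone variant (1.96 ± 0.40, adjusted p = 0.0302), and G6PC3, a glucose-6-phosphatase (1.897 ± 0.43, adjusted p = 0.0451). PVRIG, NIPSNAP1, MORC2, the inhibitory receptor LAIR1, ACO1 and the integrin subunit ITGAL followed with log2 fold changes from 1.79 to 1.44. By the naming rule, each of these genes had to differ the same way in 3 of 3 donors, which is therefore no separate result.

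Of the 34 lists, 10 passed in camera between LA and HDL, 8 lower and 2 higher with LA. Heat shock genes (17 of 20 lower, 18 when adjusted over the list alone, median -1.43) and NRF2 genes (7 of 23 lower, 13 when adjusted over the list alone, median -0.84) passed at adjusted p of 2.41e-78 and 2.14e-25, and at 0.000588 and 0.00664 with an estimated correlation. HSP90AB1 and HSPA8 were lower by log2 values of -1.62 ± 0.09 and -1.62 ± 0.10, and DNAJA1, FTL and TXNRD1 by -1.72 ± 0.15, -1.44 ± 0.09 and -1.90 ± 0.13. The lists of immediate early genes (5 of 30 lower, 6 when adjusted over the list alone; adjusted p = 3.42e-05, and adjusted p = 0.180 with an estimated correlation), NF-kB targets (3 of 23, 5 when adjusted over the list alone; 7.24e-05 and adjusted p = 0.0837 with an estimated correlation) and ATF4 targets (2 of 30, 4 when adjusted over the list alone; 0.000769 and adjusted p = 0.309 with an estimated correlation) were lower with LA. CD69, KLF6 and IRF4 had log2 fold changes of -1.68 ± 0.25, -1.11 ± 0.13 and -1.59 ± 0.22. REL, SOD2 and TNF had values of -0.99 ± 0.18, -0.98 ± 0.19 and -1.86 ± 0.31, and SLC3A2 and DDIT3 of -1.77 ± 0.12 and -1.13 ± 0.21. NFKBIA, SLC38A2 and PPP1R15A passed in edgeR with the block and not without it, with adjusted p of 0.000213, 0.00122 and 0.00331.

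The lysosome and autophagy list was also lower with LA than with HDL (2 of 30 genes; adjusted over the list alone, 6 lower and 1 higher; adjusted p = 0.00512, and adjusted p = 0.286 with an estimated correlation). The autophagosome proteins GABARAPL1 and MAP1LC3B had log2 fold changes of -1.32 ± 0.19 (adjusted p = 0.0043) and -0.59 ± 0.12 (adjusted p = 0.0293). The autophagy receptor SQSTM1 (-1.34 ± 0.32) and the sialidase NEU1 (-0.72 ± 0.17) passed in edgeR with the block and not without it, with adjusted p of 2.61e-05 and 0.00523. In the lipid peroxidation and ferroptosis list (adjusted p = 0.0236, and adjusted p = 0.180 with an estimated correlation) 1 of 15 genes was lower, SLC3A2, and 1 when adjusted over the list alone. With the block 3 were lower, including SAT1 (adjusted p = 0.0154) and the transferrin receptor TFRC (adjusted p = 0.0396), and DHODH was higher (adjusted p = 0.0460). In the p53 list (adjusted p = 0.0469, and adjusted p = 0.366 with an estimated correlation) 1 of 22 was lower, the cell cycle inhibitor CDKN1A (-0.97 ± 0.22, adjusted p = 0.0488), and 1 when adjusted over the list alone. PMAIP1, MDM2 and FAS had values of -0.88 ± 0.36, -0.41 ± 0.14 and -0.36 ± 0.12 and passed in edgeR with the block and not without it, with adjusted p of 0.000183, 0.0166 and 0.0404.

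The respiratory chain (median 0.15, adjusted p = 0.00678, and adjusted p = 0.641 with an estimated correlation) and the tricarboxylic acid cycle (median 0.14, adjusted p = 0.0296, and adjusted p = 0.232 with an estimated correlation) were higher with LA than with HDL. Of the respiratory chain genes 2 of 77 were higher, NDUFS7 (0.83 ± 0.16, adjusted p = 0.0222) and NDUFB7 (2.07-fold, adjusted p = 0.0188), and 3 when adjusted over the list alone. NDUFS8, at 0.63 ± 0.15, passed with the block (adjusted p = 0.00972), in which 6 were higher and 1 lower, NDUFV2 at -0.47. In the cycle 2 of 22 genes were higher, PDHB (0.83 ± 0.15, adjusted p = 0.0139) and MDH2 (0.78 ± 0.16, adjusted p = 0.0289), and 4 when adjusted over the list alone, while SUCLA2 and IDH3G passed in edgeR with the block and not without it. With the block 5 were higher. The block added 4 lists, cytosolic ribosomal proteins (adjusted p = 0.0428), glycolysis and hypoxia (adjusted p = 0.0360), naive and central memory genes (adjusted p = 0.0356) and pro-apoptotic genes (adjusted p = 0.0356), all lower with LA. With the block and an estimated correlation they were at adjusted p of 0.750, 0.469, 0.321 and 0.321. Without LA replicate 1 the ferroptosis, p53 and respiratory chain lists did not pass (adjusted p = 0.0932, 0.286 and 0.147). Without HDL replicate 3 the lysosome, p53 and respiratory chain lists did not (0.0517, 0.158 and 0.593), and without LA replicate 2 or HDL replicate 1 the cycle did not (0.0526 and 0.0509). The respiratory chain median of 0.15 was 0.07 without LA replicate 1 and 0.03 without HDL replicate 3.

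Between LA and HDL 93 genes were higher and 177 lower with LA, 270 of 12091, and 573 and 670 with the donor block, among them all 270 in the same direction. DESeq2 called 829. Under total-count scaling, which moved the median of all genes by 0.122, 393 passed and 64.4% of them were higher with LA, against 34.4% under TMM. The count was 111, 115, 108 and 146 without LA replicate 2, LA replicate 3, HDL replicate 2 and HDL replicate 3. Of the genes with the largest differences, 10 passed in each of the 6 fits without a library, and ACO1, AVIL, G6PC3, H2AFY2, HSPH1, LAIR1, MIR22HG, MORC2 and NIPSNAP1 did not in at least 1. The same held for CDKN1A, DDIT3, MAP1LC3B, MDH2, PDHB, NDUFS7, NDUFB7, REL, SOD2 and TNF, with adjusted p up to 0.160 (CDKN1A). The test on the 6 LA and HDL libraries alone called 112.

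To compare both responses, the log2 fold changes of LA and HDL against PBS were set side by side. Among the 146 genes that rose with HDL, the LA value was positive for 62 and negative for 84, with a median of -0.03 against 0.92 for HDL. Among the 92 that fell with HDL, the LA value was negative for 69 and positive for 23, with a median of -0.07 against -0.95. With the donor block the LA value was positive for 387 and negative for 312 of the 699 higher genes (median 0.02), and negative for 497 and positive for 178 of the 675 lower genes (median -0.08). Since these genes were picked on values against the same PBS libraries, LA values of the same sign are favoured without any LA change. No simulation was run for these sets, so the counts decide nothing on shared responses. Because edgeR called 0 genes with LA, the overlap of called genes could only be 0, as in the simulations and for independent lists, and says nothing on shared responses. DESeq2 with the block called 3 genes higher in both comparisons, ACVR1C, LOC100190986 and TTN, against 0.806 for independent lists. This count was made after the data had been seen. No simulation of the shared PBS libraries was run for it. Across the 12091 genes, which are not independent replicates, Pearson's r was 0.447, with a covariance of 0.187, and 60.6% of genes had the same sign. Because both comparisons used the same PBS libraries, simulated unchanged groups gave a mean r of 0.494 (0.452 to 0.527 over 20 simulations), a covariance of 0.155 ± 0.00927 (SD; 0.140 to 0.171) and 66.6% with the same sign. Both r and the share of genes with the same sign were below their simulated ranges (65.9 to 67.0% for the share). The simulations held HDL unchanged, while real HDL changes widen the spread of the HDL values and can lower both measures. These 2 measures therefore cannot show that LA and HDL shared less than unchanged groups would. The covariance was above its simulated range, exceeding the mean by 0.0319. Some or all of this excess may still come from the shared controls. That could not be tested, since 3 PBS libraries could not be split into parts of at least 2. The excess therefore does not show a shared response.

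**Figure D3:**
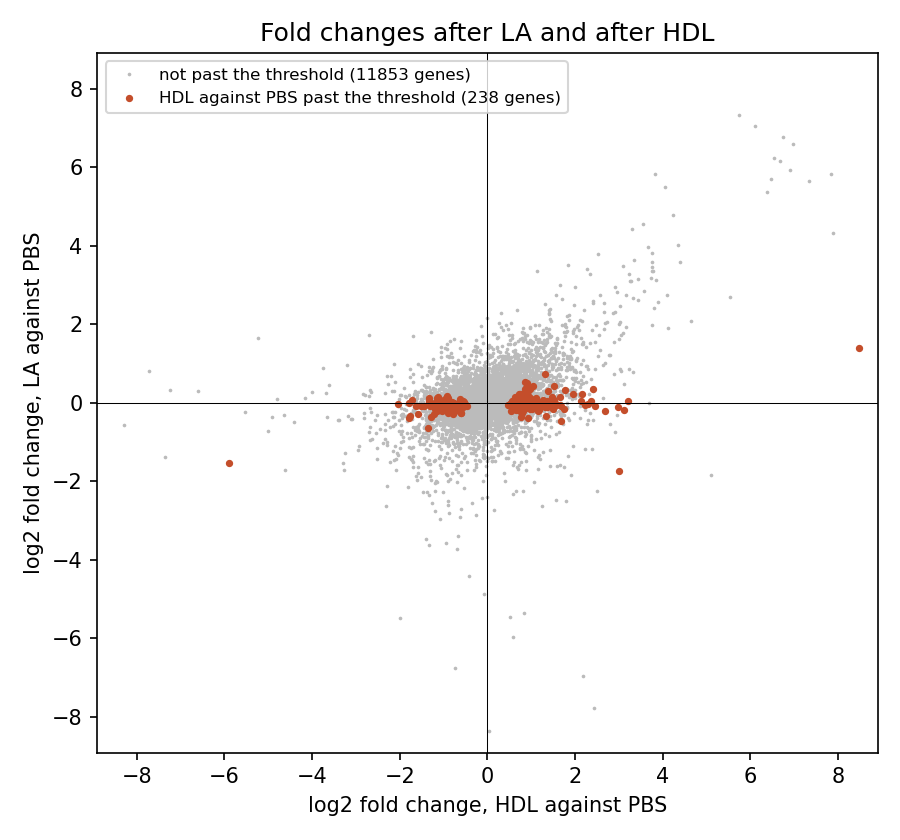
Log2 fold change of each tested gene for LA against PBS (vertical axis) and HDL against PBS (horizontal axis); red points are the 238 genes past the threshold with HDL and grey points the other 11853. The red points spread along the horizontal axis, with LA medians of -0.03 for the genes that rose with HDL and -0.07 for those that fell; both axes share the PBS libraries.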

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

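The alternatives were written before the data were examined, except the correction for GC content and transcript length and the overlap in other tools. No gene or list past the threshold changed direction under any alternative run, as far as the labels of the named genes and lists show. The count of genes past the threshold in both LA and HDL was 0 in the edgeR settings in which it was counted, 0 with DESeq2 and with limma-voom, and 3 with DESeq2 and the block. Of the named genes past the threshold, the block changed no call in either direction (79 values), and it brought 27 further values past the threshold. The other scalings ended 3 calls: MAGED1 in HDL against PBS with the size factors of DESeq2, and MAP1LC3B and CDKN1A in LA against HDL with total counts. The fit on the 6 libraries of a comparison ended 20 calls, and fits without a library ended 176 of 474 calls of named genes. With 3 libraries a group, the median SE on the log2 scale between LA and PBS was 0.307 over all tested genes and 0.166 over genes at 50 CPM or more. The causes of the differences below were not tested, except that a stricter threshold makes the count smaller by construction.

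Counts of genes are given for HDL against PBS and then for LA against HDL. They were 75 and 88 at an adjusted p below 0.01, and 104 and 129 with an absolute log2 fold change of at least 1. The replicate block, the donor as an added term, gave 1374 and 1243. With it and the size factors of DESeq2 they were 1383 and 1268, with the stricter filter of 5 CPM in 3 libraries 1595 and 1458, on the 6 libraries of the comparison 1029 and 1258, and with DESeq2 1949 and 1790. The donor as a random effect in limma-voom gave 1051 and 967, and DESeq2 without the block 931 and 829. The 6 libraries without the block gave 112 for LA against HDL. For HDL against PBS, total-count scaling gave 446, no filter 436 and the stricter filter 359. The correction for GC content and length gave 388 and 413 without the block and 1429 and 1368 with it. For LA against PBS the count was 1 with no filter, 1 with DESeq2 and 5 with DESeq2 and the block, and 0 under the other alternatives.

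Without each library in turn the counts ran from 81 to 173 and from 108 to 256, respectively. With the block and without each donor they were 977, 446 and 344, and 1073, 407 and 279. For LA against PBS the number of lists ran from 0 to 2. An estimated correlation left 2 lists for HDL against PBS and 2 for LA against HDL, with and without the block. Fry, which tests whether a list's genes move one way and not against other genes, kept 6 of the 8 lists for HDL against PBS (not ATF4 targets, adjusted p = 0.0658, nor the respiratory chain, adjusted p = 0.183) and 7 of the 10 for LA against HDL. Fry also passed 6 and 3 lists that camera did not, 12 and 10 in all. With the block fry passed 15 and 16. These included ATF4 targets (adjusted p = 0.0242 and 0.0197) and, for LA against HDL, p53 targets (adjusted p = 0.0321), but not the respiratory chain (adjusted p = 0.124 and 0.204). The stricter filter ended the calls of the ferroptosis (adjusted p = 0.0656) and p53 (adjusted p = 0.0668) lists in LA against HDL. The correction for GC content and length gave 14 lists for HDL against PBS, and 17 with the block. The correlation of LA and HDL fold changes was 0.305 with the stricter filter and ran from 0.350 to 0.650 without each library, with the 3 highest values (0.6085, 0.616 and 0.650) where a PBS library was left out.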

Other observations

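Besides the genes named by the rule, further HDL-responsive genes were picked after their values were seen. The ubiquitin gene UBB rose with HDL from 1103 ± 113 to 2932 ± 451 CPM (SD, n = 3; edgeR log2 1.41 ± 0.14, adjusted p = 0.000475). The nuclear export receptor XPO1 rose from 87.6 ± 24.2 to 340 ± 14.2 CPM (1.96 ± 0.20, adjusted p = 0.000516), and the HSP90 cochaperones STIP1 and AHSA1 rose by log2 1.32 ± 0.11 (adjusted p = 0.00012) and 0.93 ± 0.12 (adjusted p = 0.00263). The cytosolic chaperonin, which folds actin and tubulin, had positive values for 9 of 9 tested subunits (median 0.485, and 0.385 under total-count scaling). Of these 2 rose, TCP1 and CCT4, and 6 with the donor block. The LA median of the same subunits was -0.07. Of 38 proteasome subunits 25 had positive values, with 1 higher and 1 lower.

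Among T cell surface and effector genes, also picked after their values were seen, ICOS and CD28, costimulatory receptors, rose with HDL from 264 ± 40.8 to 455 ± 58.5 CPM (log2 0.79 ± 0.15, adjusted p = 0.0261) and from 272 ± 11.8 to 452 ± 61.3 CPM (0.73 ± 0.13, adjusted p = 0.0149). The cytokine IL32 fell from 1016 ± 45.7 to 475 ± 7.65 CPM (-1.10 ± 0.09, adjusted p = 0.000114) and CD3E, a chain of the T cell receptor complex, from 516 ± 38.7 to 312 ± 42.8 CPM (-0.73 ± 0.13, adjusted p = 0.020). Each of these rose or fell in 3 of 3 donors. CD79B, a B cell marker, was at 30.4 ± 5.30 CPM in PBS and 16.25 ± 4.05 CPM in HDL and passed in edgeR with the block (adjusted p = 0.0236) and not without it (adjusted p = 0.0821).

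For the patterns below, the correction for GC content and length, the monocyte test and the bootstrap error were chosen after the data had been seen. Of 43 tested heat shock and NRF2 genes, 25 were called higher in the HDL libraries. A bias of GC content or transcript length as the whole cause was argued against: with each library's trend removed, 25 of these 25 stayed past the threshold, and the list medians were 1.51 and 1.03. The 25 genes had a median GC content of 48.1%, against 47.8% for all tested genes. Removing a GC trend could therefore move them little as a set. Monocytes, which express HMOX1 and would have been largely removed by a sort for CD4+ T cells, were argued against as its source: LYZ, S100A8, S100A9, CST3, TYROBP and FCER1G together reached at most 0.131 of the CPM of HMOX1 in any HDL library, and none was above 2.94 CPM in the mean of any group. A direct response to HDL stays open as a hypothesis, and so does a response to another component of the HDL preparation, which no library here tests.

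The lists of respiratory chain and mitochondrial ribosome genes had a joint median log2 fold change of -0.208 over 152 genes with HDL, although 3 and 0 genes fell, 1 ribosome gene rose, and neither list passed with an estimated correlation (adjusted p = 0.523 and 0.373). A GC or length bias was a candidate explanation, since genes that fell with HDL under the block had a median length of 2671 nucleotides and a GC content of 51.4%, against 3944 and 43.2% for those that rose. With the trend removed the median was -0.17. This met the bound of -0.167 set in advance against a bias, but by less than its bootstrap error of 0.031. The bootstrap resampled the 152 genes as if they were independent. Its error therefore leaves out the correlation between genes and the spread between libraries. A partial contribution of GC and length cannot be told apart from a change in these genes. After the correction both lists passed with the preset correlation (adjusted p = 0.001 and 0.0371) and neither did with an estimated correlation (adjusted p = 0.349 and 0.250).

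The genes of this last pattern lay outside the naming rule and were picked after the metallothionein values had been seen. MT2A, a metallothionein, which binds zinc, was at 4.65 ± 0.78 CPM in PBS and 1.17 ± 0.187 CPM in HDL. It was not past the threshold without the block (adjusted p = 0.0543) and was lower with it (adjusted p = 0.0325). MT1F and MT1X passed in neither fit (adjusted p = 0.0908 and 0.151 with the block). A loss of transcripts of this length was argued against, since 164 tested genes of similar length and abundance had a median log2 fold change of 0.152. Length was that of each gene's longest transcript, with a median of 690 nucleotides for the 3 metallothioneins. A loss limited to shorter transcripts was therefore not tested. The 164 genes were not matched on GC content, so a GC bias was not tested here. The median GC content was 59.9% in the 3 metallothioneins and 47.8% in all tested genes. Less available zinc is a hypothesis that the data left open: the zinc exporter SLC30A1 was at -0.737 ± 1.01 with the block, which decides nothing, while the importer SLC39A10 was higher with the block (0.76 ± 0.14, adjusted p = 0.00537) and not past the threshold without it (adjusted p = 0.123). The list of metallothioneins and zinc response genes as a whole did not pass in camera (adjusted p = 0.169) and passed as lower in fry without the block (adjusted p = 0.0314), but not with it (adjusted p = 0.102).

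Each comparison was refitted on every split of its 6 libraries into groups of 3, with the same 12091 genes. There are 10 such splits, too few for a share under 0.05. For HDL against PBS the real split called 205 genes and the highest other 1, so 1 split of 10 was as large; for LA against HDL the numbers were 105 and 2, again 1 split. For LA against PBS the real split called 0 and the highest other 2, so all 10 were as large. For lists, the real split and the highest other gave 9 and 9 in HDL against PBS (2 splits as large), 9 and 14 in LA against HDL (3 splits) and 0 and 5 in LA against PBS (10 splits). In the 4 splits that part all pairs of a donor, fitted with the block, the real and the highest other counts were 1032 and 0, 1232 and 0, and 0 and 1, in the same order of comparisons.

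Camera's direction and the median differed in sign between HDL and PBS for the lists of mTORC1 and MYC translation genes (median -0.06, mean 0.01, test up), SREBP2 targets (median -0.03, mean 0.01, test up), IL-2 and STAT5 targets (median 0.11, mean -0.02, test down) and effector and memory genes (median 0.03, mean -0.16, test down), none of which passed. The mean had the other sign from the median and the test for anti-apoptotic genes (median 0.05, mean -0.20), lipid droplet genes (median 0.08, mean -0.08) and cell cycle genes (median 0.05, mean -0.09), which did not pass either.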
